A study of Danio rerio with 6 samples.

How the data were processed

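RNA was extracted with TRIzol and a column kit from dissected adult livers and sequenced as standard Illumina libraries, per the labels' protocols: 3 libraries of capn3b mutants and 3 of wild type AB fish. The authors deposited a table of FPKM values for 23354 genes with Ensembl identifiers, names and positions, and for each library a list of splicing, start and end events with the FPKM of the transcripts behind them. Per the submitters' processing notes, DESeq2 was among the authors' tools and GRCz11 was the genome build; the aligner, the counter, the annotation release and the tool behind the event lists are not given in the sources used here. Gene names are those of the deposited table; 21036 of the 23354 identifiers matched the gene name table used to resolve list members.

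FPKM values are not counts, so the tests were run on log2(FPKM + 1). Within a gene the deposited values are whole multiples of 1 read's worth. With depth and gene length solved for, 99.987% of genes gave whole reads in all 6 libraries within 0.05 reads, which sets the depth at 16858409 to 19492592 reads. On simulated values the recovery returned every read of 98.99% of 22650 genes. Recovered reads serve for detection floors (3 reads), counting intervals (95%, binomial) and an added alternative. Intervals and floors cover counting error only, since reads are not independent molecules.

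Genes with at least 1 FPKM in at least 3 of 6 libraries were tested with limma 3.58.1 (R 4.3.3): a linear model of genotype, moderated with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over 11164 genes and a threshold of 0.05. A count of genes changed at least 2-fold adds an absolute log2 fold change of at least 1. Standard deviations are between the 3 libraries of a group. On simulated counts for this comparison, over 11204 genes, 86.6% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, and 6.61% of calls were false. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over 34 lists. In the simulation 2 of 2 changed lists and 0 of 34 unchanged ones were called. The simulated genes were drawn independently, and the changed lists held changed genes only. This result therefore says nothing about false calls on lists of correlated genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.

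Named genes follow a rule fixed before the data were examined: capn3b, capn3a and any other calpain system gene past the threshold; the 10 risen and 10 fallen genes with the largest log2 fold change among changed genes whose groups do not overlap and that carry a symbol other than a clone or database name; and the 3 members with the smallest p of each list that moved and of the complement, acute phase, interferon, NF-kB, pattern recognition and antigen presentation lists, among others. Some genes under this rule, and a list, are not reported here. Of 79 such genes 75 passed the threshold. The span of 14 of them overlaps another gene of the table, and the counting is not stated to use strand, so their reads may be shared: a2ml, mhc1zba, abcg8, c3a.2, c9, alas2, pdk4, lpin1, pck1, ccl19a.1, mavs, pycard, wdr75 and cyp2k22.

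Alternatives fixed before the data were examined were a pseudocount of 0.1, median scaling, quantile normalization, the replicate number as a block, no expression filter, a filter of 5 FPKM, robust moderation, each library left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were limma voom on the recovered reads, the counts and list tests without genes within 10 Mb of capn3b, and a test of exon skipping.

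For exon skipping, events were matched between libraries by their coordinates, and percent inclusion, the FPKM of isoforms with the exon over that of both forms, was tested with limma without a trend. The rule recorded before the test took each event whose forms summed to at least 1 FPKM in every library, 1604 events. Of these, 698 had the same percent inclusion in every library, to within an SD of 1e-09 percent. Such events cannot be fitted and entered the adjustment with a p-value of 1. This handling was settled after a first count had been seen: a first version treated only the 529 events with an SD of exactly 0 in this way and gave 2 events past the threshold. The other 169 events differed by rounding error alone, the smallest SD among the 906 varying events being 0.789 percent, and including them lowered limma's prior variance from 164 to 1.76. The first version and the test of the 906 varying events alone are both given as alternatives. On simulated inclusion over 1604 events, 97% of 100 shifted events were recovered and 3% of calls were false. All shifts had the same large size, and the noise was binomial alone, with no added variation between libraries. These shares therefore do not give the power for the real events.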

Results

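Gene expression was measured by RNA sequencing in 6 libraries from dissected adult zebrafish liver, 3 of capn3b mutants and 3 of wild type AB fish, AB being a laboratory strain. The gene capn3b is one of a pair of zebrafish genes for calpain 3, a calcium-dependent cysteine protease. The series asked which genes differ between the mutant and the wild type liver, and its title places the answer in the innate immune response. The values are FPKM, reads scaled to gene length and library depth, for 23354 genes. The reads behind the depth scale, recovered from the values, numbered 17905457, 17906695 and 18470779 in the mutant libraries and 19492592, 17268036 and 16858409 in the wild type libraries, so that the deepest library held 1.16 times the reads of the shallowest. The 10 most abundant genes took 31.7% to 34.6% of all FPKM in a library. Mitochondrial genes took 4.73%, 4.45% and 5.45% of the FPKM in the mutant libraries and 8.57%, 6.22% and 6.77% in the wild type libraries. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The sex of the fish is not given in the labels either, so a difference in sex cannot be told apart from genotype.

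The mutated gene was at or under the detection floor in both genotypes and therefore checks no label. For capn3b (ENSDARG00000043035, chromosome 20, 26056028 to 26102200, coordinates as in the deposited table, with GRCz11 as the build in the submitters' processing notes), 1 read was recovered in mutant replicate 3 and 0 reads in each of the other 5 libraries. A count of 3 reads, the limit that a count of 0 allows, corresponds to 0.0514 to 0.0594 FPKM for this gene, and it covers counting error only. Its span overlaps znf106b. The second copy, capn3a (ENSDARG00000041864, chromosome 17, 45191718 to 45363385), had 0 reads in the mutant libraries and 0, 3 and 1 reads in the wild type libraries. Of the 10 tested members of the calpain system, capn2b was past the threshold, at 2.5 ± 0.23 FPKM in the mutant and 1.14 ± 0.41 in the wild type (SD, n = 3 each). Its log2 fold change was 0.73 with a standard error of 0.17 and an adjusted p of 0.0352 (limma, Benjamini-Hochberg), which ranged from 0.0321 to 0.11 over the alternatives and lost the call in 9 of 13 of them. Below the expression filter, and singled out after their values were seen, capn8 had 0 mutant reads against 61, 29 and 46 wild type reads, and capn2l had 22 mutant reads against 221 wild type reads in total. With no filter both passed the threshold (adjusted p = 0.0274 and 0.0361, limma) and capn2b did not (0.0979). The spans of these 2 genes on chromosome 22 overlap each other, so the counting could have split their reads.

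Mutant and wild type liver libraries differed widely. Of 11164 genes with at least 1 FPKM in at least 3 libraries, 1268 changed, 660 of them higher and 608 lower in the mutant, and 623 of the 1268 changed at least 2-fold (310 higher, 313 lower; limma, adjusted p under 0.05). All mutant libraries lay above or below all wild type libraries in 3771 tested genes, 33.8%, where chance gives 10%, and in each of the 1268 changed genes. The first principal component held 58.9% of the variance and separated the genotypes. Leaving out 1 library moved the count by over 1.5 times for mutant replicate 1 (516 genes), mutant replicate 2 (536), wild type replicate 1 (801) and wild type replicate 2 (414), and that of genes changed at least 2-fold for mutant replicate 2 (408) and wild type replicate 2 (334). Testing all genes with a value above 0 gave 592 changed genes, 358 of them at least 2-fold, and a filter of 5 FPKM gave 412 changed at least 2-fold.

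The largest rises included those of ntd5, lect2l and vipb. The secreted factor gene lect2l had a log2 fold change of 4.88 (standard error 0.82, adjusted p = 0.0125), with 27.7, 406 and 86.1 FPKM in the mutant libraries against 1.41 to 3.58 in the wild type libraries. Without wild type replicate 2 its adjusted p was 0.0533. The log2 fold change was 4.89 for ntd5, 3.98 for vipb, which encodes a vasoactive intestinal peptide, and 3.69 for pltp, the phospholipid transfer protein. The proteoglycan gene esm1 had 111, 252 and 72.2 FPKM in the mutant libraries against 8.42, 3.32 and 17.7 in the wild type libraries. The transcription factor genes junba and egr1 rose by 3.54 and 2.73 on the log2 scale, to means of 55.6 and 93.5 FPKM in the mutant. The transporter gene flvcr2a rose to a mean of 12.0 FPKM, and its 10 wild type reads all lay in replicate 3. The crystallin gene crygs1 had 0 wild type reads and 70, 41 and 205 mutant reads, at least 103-fold higher against a floor of 3 reads over the group, and at least 55.4-fold without mutant replicate 3. The cytochrome P450 gene cyp3c3 completed the 10 largest, with a log2 fold change of 3.01, and its adjusted p of 0.0206 rose above 0.05 with no filter, without mutant replicate 1 and without wild type replicate 2 (range over the alternatives 0.011 to 0.0784). Without mutant replicate 2 the ratio of mean FPKM went from 68.3 to 22.4 for lect2l, from 26 to 17.3 for pltp, from 14.8 to 9.34 for esm1 and from 13.4 to 6.88 for cyp3c3. Without wild type replicate 3 it went from 40.6 to 162 for ntd5, from 13.9 to 23.1 for junba and from 14.8 to 24.7 for esm1, and without wild type replicate 2 from 46 to 73 for vipb. The log2 values are on the log2(FPKM + 1) scale, which understates the change of low genes.

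The largest falls included several genes with hardly a read in the mutant. The cytochrome P450 gene cyp2p9 (ENSDARG00000022631, chromosome 20, 25682537 to 25685779) had 0 reads in every mutant library and 2590, 898 and 2590 in the wild type libraries, at least 2040-fold lower against a floor of 3 reads over the group. Its neighbour cyp2p10 had 0 mutant and 427 wild type reads, at least 142-fold lower. Reads of such closely related family members may not be separable. The methionine salvage gene apip had 2 mutant reads, both in replicate 2, and 342 wild type reads, a ratio of 173 with a 95% counting interval of 47.6 to 1440. The log2 fold change was -3.97 for cyp39a1, an oxysterol hydroxylase on the same chromosome, -4.51 for cbln6, -2.94 for mthfsd and -2.90 for cyp2x10.2. Without mutant replicate 1 the wild type to mutant ratio of mean FPKM went from 83.8 to 138 for cyp39a1 and from 27.7 to 68.7 for mthfsd, and the 21 mutant reads of cbln6 all lay in replicate 3. The gluconeogenic gene pck1 fell from 76.1 ± 36.7 to 8.37 ± 1.3 FPKM and the glutamine synthetase gene glula from 63.0 to 7.14 FPKM. The ribonuclease gene rnasel2 had 2 mutant reads, both in replicate 1, against 13343, 8082 and 124 wild type reads, and without wild type replicate 1 its ratio of mean FPKM went from 10400 to 6390. Its adjusted p was 0.022 and lay between 1.28e-05 and 0.391 over the alternatives, and the call was lost in 6 of 14, among them those without mutant replicate 1 or 2 and without wild type replicate 1 or 2. The mitochondrial carrier gene slc25a38a, with an adjusted p of 0.0459, lost its call in 9 of 14 alternatives (highest adjusted p 0.149).

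**Figure D1:**
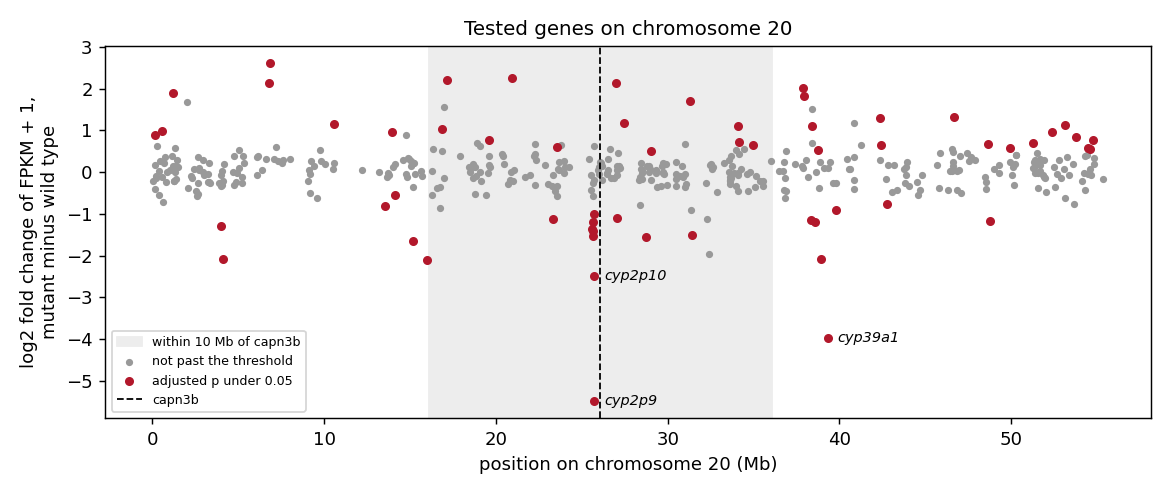
Tested genes along chromosome 20, with the position in megabases on the horizontal axis and the log2 fold change of FPKM + 1 (mutant minus wild type) on the vertical axis. Each point is a gene, red where the adjusted p is under 0.05; the dashed line marks capn3b and the grey band the 10 Mb on either side. The fitted value of cyp2p9 (-5.49), which has 0 mutant reads, lies close to capn3b, and cyp39a1 (-3.97) lies outside the band.

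Complement genes, NF-kB targets and genes of antigen presentation were higher in the mutant as groups. Of 32 tested complement genes, 11 rose, 1 fell and 20 did not pass (15 rose and 2 fell when adjusted over the list alone). The central component gene c3a.2 rose from 485 ± 43 to 1010 ± 217 FPKM, the pore-forming component gene c9 from 2126 ± 152 to 3826 ± 604, and the factor H-like gene cfhl5 from 167 ± 40 to 370 ± 57 (SD, n = 3 each). The list's camera adjusted p was 0.00134, and the adjusted p = 0.355 with an estimated correlation. Of 34 NF-kB targets, cytokines and chemokines, 11 rose, 1 fell and 22 did not pass (17 and 2 over the list alone), among them tnfaip2b, a target of tumour necrosis factor, from 0.452 to 7.71 FPKM, and the chemokine genes ccl19a.1, from 5.89 to 25.8, and cxcl12a, from 1.1 to 3.03. This list had a camera adjusted p of 2.49e-05, and an adjusted p = 0.419 with an estimated correlation. Antigen processing and presentation moved up with 2 of 27 members past the threshold (2 over the list alone), the MHC class II gene mhc2dab, from 12.8 to 53.1 FPKM, and the MHC class I gene mhc1zba, from 55.2 to 98.8. In wild type replicate 3 its mean log2 level was 3.94, above the 3.87 of mutant replicate 2. Its camera adjusted p was 0.0013, with an adjusted p = 0.625 with an estimated correlation. Neighbouring copies overlap c3a.2, ccl19a.1 and mhc1zba, so their reads are uncertain. The c9 call was lost with no filter and without mutant replicate 1, mutant replicate 2 or wild type replicate 2 (highest adjusted p 0.0786), that of cfhl5 without wild type replicate 2 (0.0537), and that of mhc1zba in 8 of 14 alternatives (highest 0.101).

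The acute phase, interferon and pattern recognition lists did not pass as groups. Among 33 acute phase genes, 6 rose and 4 fell (14 and 6 over the list alone; camera adjusted p = 0.0586, and adjusted p = 0.389 with an estimated correlation). The antitrypsin-family gene serpina1l rose from 4323 ± 282 to 9601 ± 1136 FPKM, whereas a2ml, a protease inhibitor of the macroglobulin family, fell from 114 to 54.9. Of 30 interferon-stimulated genes 3 rose and none fell (9 and 0 over the list alone; camera adjusted p = 0.0586, and adjusted p = 0.625 with an estimated correlation). They were the ubiquitin-like modifier gene isg15, from 9.27 ± 1.65 to 36.3 ± 12.4 FPKM, the transcription factor gene irf7, from 1.60 to 4.25, and the chemokine gene cxcl11.1, from 0.364 to 2.65. Of 15 pattern recognition genes, the adaptor genes myd88 and pycard rose by 0.84 and 0.67 on the log2 scale and mavs, an adaptor of RNA sensing, fell by 0.71 (2 and 1 over the list alone; camera adjusted p = 0.485, and adjusted p = 0.737 with an estimated correlation). The calls of cxcl11.1, myd88, mavs and pycard were lost in 5 of 13, 5 of 14, 7 of 14 and 10 of 13 alternatives, and that of a2ml without mutant replicate 1 or wild type replicate 2 (highest adjusted p 0.0546). Without wild type replicate 3 the ratio of mean FPKM of cxcl11.1 went from 7.29 to 16.3.

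**Figure D2:**
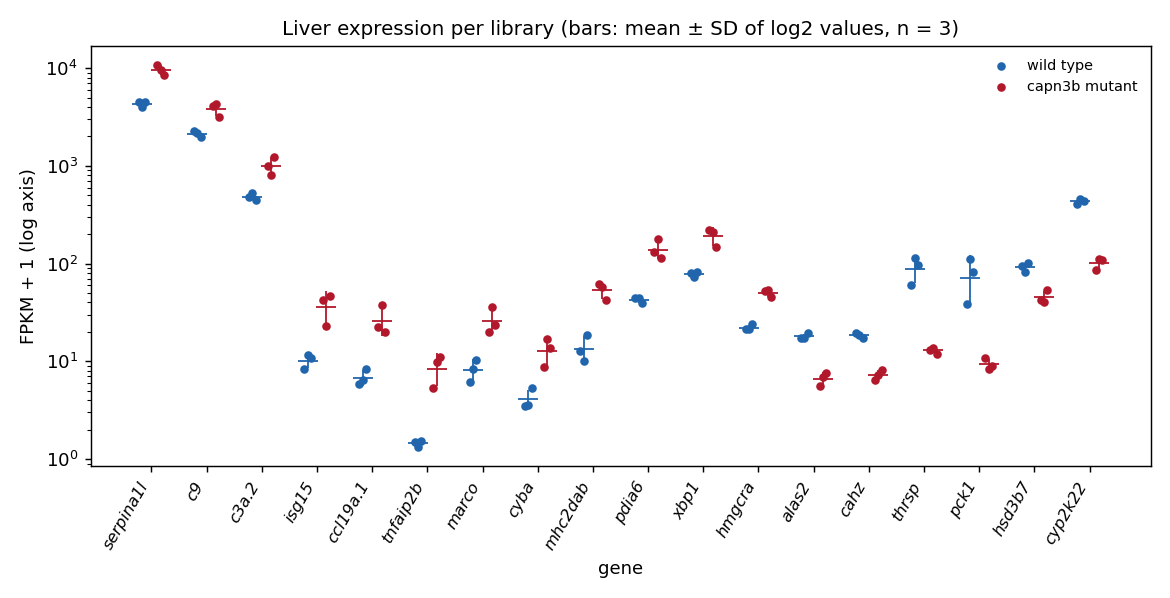
FPKM + 1 on a log axis for 18 genes, in each of 3 wild type (blue) and 3 mutant (red) libraries; horizontal bars and whiskers are the mean and SD of the log2 values. The genotypes do not overlap in any of the 18 genes: serpina1l, for example, averages 9601 FPKM in the mutant and 4323 in the wild type, and cyp2k22 averages 102 and 433.

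Markers of blood cells moved in opposite directions, and this stands beside the immune groups above. Of 24 macrophage markers 11 rose and none fell (20 and 0 over the list alone), with a median log2 fold change of 0.95. The scavenger receptor gene marco rose from 7.31 to 25.4 FPKM, mpeg1.2, a perforin-like macrophage gene, from 1.16 to 4.40, and the myeloid transcription factor gene irf8 from 3.55 to 8.26. The camera adjusted p was 2.09e-08, and the adjusted p = 0.389 with an estimated correlation. Of 12 neutrophil markers 7 rose (10 over the list alone), with a median of 1.48, among them cyba, a subunit of the phagocyte oxidase, from 3.15 to 12.2 FPKM, and the collagenase gene mmp13a, from 0.242 to 2.59. Here the camera adjusted p was 2.2e-05, with an adjusted p = 0.389 with an estimated correlation. Of 15 erythrocyte markers 10 fell and none rose (12 and 0 over the list alone), with a median of -0.68. The carbonic anhydrase gene cahz fell from 17.6 ± 1.1 to 6.29 ± 0.85 FPKM, alas2, the erythroid enzyme of haem synthesis, from 17 ± 1.1 to 5.66 ± 1.02, and si:ch211-5k11.6 from 17.2 to 1.78 (SD, n = 3 each). The camera adjusted p was 2.09e-08, and the adjusted p = 0.355 with an estimated correlation. Hepatocyte markers moved down, with 5 of 25 fallen and 1 risen (10 and 3 over the list alone; camera adjusted p = 0.00102, and adjusted p = 0.419 with an estimated correlation): ahsg2, a fetuin gene, fell from 870 to 415 FPKM and fahd2a from 35.7 to 15.3, while the tyrosine aminotransferase gene tat rose from 105 to 245. The calls of mpeg1.2, irf8, cyba and mmp13a were lost in 3, 3, 1 and 4 alternatives, each time including that without wild type replicate 2, with highest adjusted p of 0.0623, 0.0566, 0.0522 and 0.0923 over all alternatives. The ratio of mean FPKM of mmp13a went from 10.7 to 21 without wild type replicate 1, and that of si:ch211-5k11.6, wild type over mutant, from 9.67 to 15.1 without mutant replicate 3.

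The unfolded protein response, which serves protein folding in the endoplasmic reticulum, was higher in the mutant as a group. Of 35 tested genes of this response 18 rose, none fell and 17 did not pass (27 rose and 0 fell when adjusted over the list alone), with a median log2 fold change of 0.65. The disulfide isomerase gene pdia6 rose from 41.9 ± 3.1 to 141 ± 33 FPKM, xbp1, a transcription factor of this response, from 76.9 ± 4.8 to 192 ± 41, and atf3, a stress-responsive transcription factor gene, from 1.94 ± 0.50 to 11.8 ± 6.8 (SD, n = 3 each). The camera adjusted p was 7.16e-10, and the adjusted p = 0.389 with an estimated correlation. Of these genes, pdia6 lies within 10 Mb of capn3b (chromosome 20, 31314616 to 31328243). Without genes in that window the camera adjusted p of the list was 1.57e-09. The proteasome list moved up by a median of 0.45 with 30 of 31 genes higher, though 2 passed the threshold singly, adrm1 and psmd11a, and 0 when adjusted over the list alone (camera adjusted p = 1.7e-05, and adjusted p = 0.599 with an estimated correlation). In wild type replicate 3 the mean log2 level of this list was 4.26, against 3.95 in each of the other wild type libraries and 4.42, 4.65 and 4.29 in the mutant libraries. Ribosome biogenesis moved up by a median of 0.16 with 1 of 55 genes past the threshold, wdr75, and 0 when adjusted over the list alone (camera adjusted p = 0.0321, and adjusted p = 0.756 with an estimated correlation), and lost its call at a filter of 5 FPKM and without mutant replicate 2, wild type replicate 1 or wild type replicate 2 (highest adjusted p 0.308). Its mean log2 level in wild type replicate 3 was 3.19, above those of mutant replicates 1 and 3 and against 2.73 and 2.81 in the other wild type libraries, and without that library the adjusted p was 0.000368. The calls of adrm1, psmd11a, and wdr75 were lost in 6 to 10 alternatives each (highest adjusted p 0.149), and that of atf3 without wild type replicate 2 (0.0528).

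Metabolic genes moved in both directions, beside the lower hepatocyte markers. Of 26 cholesterol synthesis genes 12 rose and none fell (17 rose and 1 fell over the list alone). Transcripts of hmgcra, the rate-limiting reductase, rose from 21.2 ± 1.4 to 49.2 ± 4.5 FPKM, of dhcr7, a late enzyme of the pathway, from 5.1 ± 0.45 to 11.9 ± 1.9, and of ldlrb, a lipoprotein receptor, from 1.42 to 3.74 (camera adjusted p = 1.63e-07, and adjusted p = 0.389 with an estimated correlation). Of 19 fatty acid synthesis genes 5 fell and 1 rose (7 and 2 over the list alone). The lipogenic regulator gene thrsp fell from 90.1 ± 27.5 to 11.9 ± 0.9 FPKM, the elongase gene elovl2 from 52.9 to 13.3 and the phosphatidate phosphatase gene lpin1 from 23.8 to 4.61 (camera adjusted p = 0.00191, and adjusted p = 0.355 with an estimated correlation). Of 32 fatty acid oxidation genes 4 fell (4 over the list alone), among them cpt1b, the carnitine transferase of fatty acid import, from 241 to 113 FPKM, pdk4 and eci1 (camera adjusted p = 0.000392, and adjusted p = 0.485 with an estimated correlation). Bile acid synthesis and transport had 7 of 17 genes fallen (9 fell and 1 rose over the list alone), including the steroid dehydrogenase gene hsd3b7, from 91.3 to 44.5 FPKM, and the transporter genes slco1d1 and abcg8, though the mean log2 level of the list in mutant replicate 3, 4.45, lay above the 4.42 of wild type replicate 3 (camera adjusted p = 0.000404, and adjusted p = 0.389 with an estimated correlation). Of 42 xenobiotic metabolism genes 11 fell and none rose (19 fell and 3 rose over the list alone), led by cyp2p9, cyp2p10 and cyp2k22, the last from 433 ± 21 to 102 ± 14 FPKM (camera adjusted p = 6.46e-07, and adjusted p = 0.389 with an estimated correlation). Of these, cyp2p9 and cyp2p10 lie within 10 Mb of capn3b. Without genes in that window the camera adjusted p of the list was 0.000781. Clock genes were lower, with 3 of 22 fallen (6 over the list alone): the cryptochrome gene cry1ab, from 5.16 to 1.31 FPKM, ciarta and rorcb (camera adjusted p = 0.000392, and adjusted p = 0.389 with an estimated correlation). The calls of pdk4 and eci1 were each lost in 6 of 14 alternatives, that of rorcb in 5 and that of cpt1b in 3, among them those without mutant replicate 1 and without wild type replicate 2 (highest adjusted p 0.0977, 0.113, 0.0774 and 0.0768). Those of elovl2, lpin1 and abcg8 were lost without wild type replicate 2 alone (0.053, 0.0539 and 0.0583), and that of slco1d1 without mutant replicate 1 alone (0.0501).

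**Figure D3:**
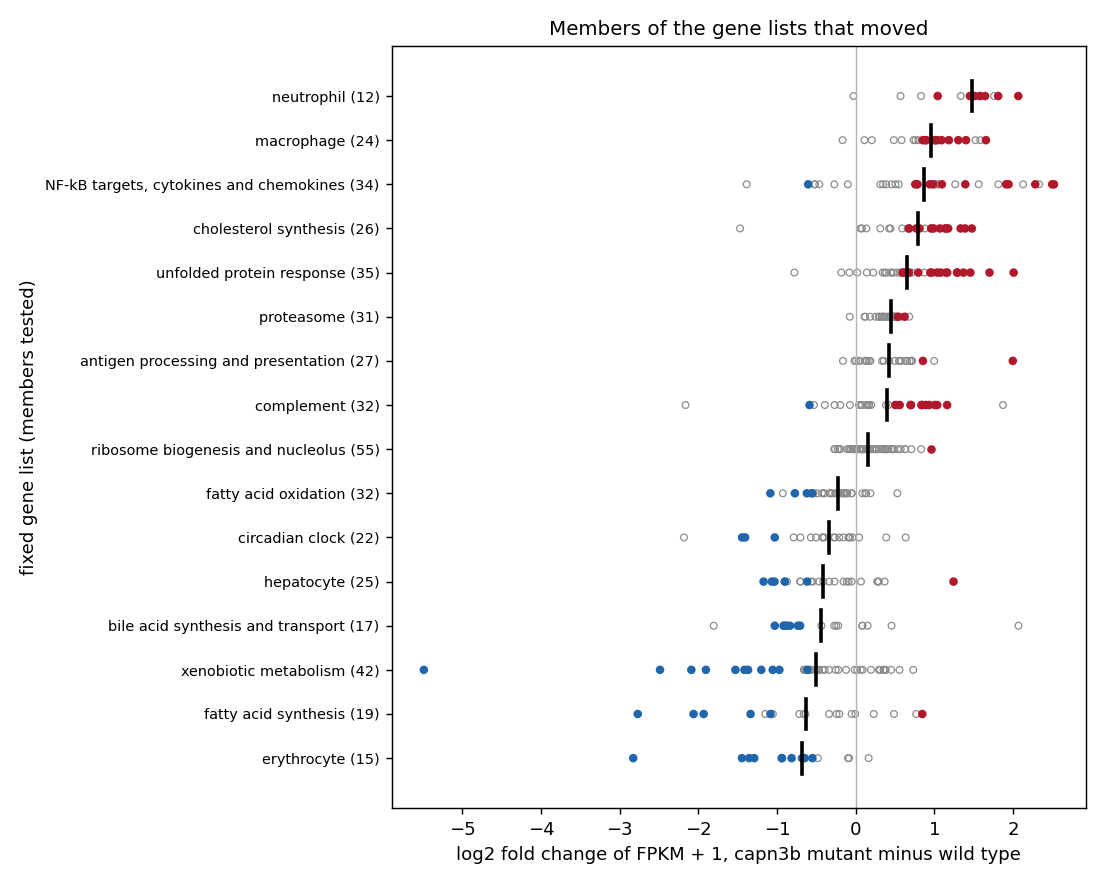
Log2 fold change of FPKM + 1 (mutant minus wild type, horizontal axis) of each tested member of the 16 gene lists with a camera adjusted p under 0.05, with the number of members tested in brackets. Filled points passed the threshold (red higher, blue lower in the mutant), open points did not, and black bars are list medians, from 1.48 for neutrophil markers to -0.68 for erythrocyte markers.

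In all, 16 of 34 lists moved by camera with its preset correlation, 9 up and 7 down. With an estimated correlation none did, the lowest adjusted p being 0.355. Correlation alone does not account for this loss. The estimates for fatty acid synthesis (-0.0123) and complement (0.0155) lay near the preset 0.01. Their unadjusted camera p still rose from 0.000844 to 0.0222 and from 0.000551 to 0.0313. The adjusted p with an estimated correlation, given for the lists above, therefore does not measure the correlation of members alone. Other groupings of the same 6 libraries moved up to 15 lists and gave 0 changed genes. Those groupings mix the genotypes, which widens the spread within groups and keeps part of the genotype difference, so neither is a null count. By fry's directional test, which does not compare a list with other genes, 5 of the 16 lists did not pass: NF-kB targets, cytokines and chemokines (adjusted p = 0.0505), fatty acid oxidation (0.0538), proteasome (0.102), antigen processing and presentation (0.156) and ribosome biogenesis (0.372). Other lists that did not pass were T and NK cell (camera adjusted p = 0.0617), stellate cell and fibroblast (0.233), cholangiocyte (0.233), calpain system (0.32), glycolysis and gluconeogenesis (0.393), cell cycle (0.441), intestine (0.485), endothelial cell (0.579), oxidative stress response (0.672), oxidative phosphorylation (0.692), cytosolic ribosomal proteins (0.713), heat shock (0.73), pancreas (0.787) and thrombocyte (0.985). Some of these lists passed in other settings. Interferon-stimulated genes and T and NK cell markers moved up with median scaling (adjusted p = 0.0412 and 0.0468) and without mutant replicate 2 (0.00276 and 0.0297), and the first also without wild type replicate 1 (0.0454) or 2 (0.0493). The acute phase list moved up with quantile normalization (0.0132), by fry (0.0216) and without mutant replicate 2 (0.049), mutant replicate 3 (0.0334) or wild type replicate 2 (0.0291). Stellate cell and fibroblast markers moved up with no filter (0.0355) and without mutant replicate 2 (0.0434), and the calpain system by fry (0.00296). Pancreas markers stood apart in wild type replicate 1, with a mean log2 level of 5.41 against 3.24 and 3.19 in the other wild type libraries and 3.28, 4.31 and 4.70 in the mutant libraries, and moved up without it (0.000102). Cell cycle genes had a mean log2 level of 2.33 in wild type replicate 3, against 1.06 and 1.1 in the other wild type libraries, and moved up without it (0.00047). Cytosolic ribosomal proteins moved down without mutant replicate 1 (0.0168) or wild type replicate 1 (0.046) and up without wild type replicate 2 (0.0465). In glycolysis and gluconeogenesis the median was -0.17 and the mean 0.077, and in the intestine list 0.031 and -0.491. The oxidative stress response had a median of -0.052 and a mean of 0.023. Median and mean were above 0 and the test pointed down for oxidative phosphorylation, cytosolic ribosomal proteins and heat shock. Too few members were tested of the oestrogen-responsive (2), B cell (4), skeletal muscle (2) and ovary (1) lists. In the oestrogen-responsive list 1 of the 2 genes fell and the median log2 fold change was -0.87, too few genes to tell the sex of the fish.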

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

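Tests chosen after the data were seen were voom, the counts and list tests without genes near capn3b, and all of exon skipping. The counts depended on the filter and on single libraries more than on scaling. Every one of the 1268 changed genes that an alternative tested kept its direction there. The groups of these genes did not overlap, so leaving out a library or changing the pseudocount, filter or moderation could not reverse it. The number of changed genes, 1268, was 592 with no expression filter, and 414 to 1134 with 1 library left out (516 without mutant replicate 1, 536 without mutant replicate 2, 801 without wild type replicate 1, 414 without wild type replicate 2). The number changed at least 2-fold, 623, was 358 with no filter, 412 at a filter of 5 FPKM, and 334 to 691 with 1 library left out. A smaller set of libraries leaves fewer residual degrees of freedom, and no filter tests more genes; the 5 FPKM filter tests fewer. The other settings stayed within 1.5 times: 1186 changed genes with a pseudocount of 0.1, 1420 with median scaling (43% higher, against 52.1%), 1380 with quantile normalization, 1296 with robust moderation, 1364 by voom on recovered reads and 1237 without genes within 10 Mb of capn3b. The 16 lists that moved became 0 with an estimated correlation, 14 by fry's directional test, which did not call 5 of the 16 (NF-kB targets, fatty acid oxidation, proteasome, antigen presentation and ribosome biogenesis) and called lists that camera did not, and 29 by fry's mixed test, which asks whether genes change in either direction; leaving out 1 library gave 17 to 19. The 0 exon skipping events became 0 to 1 with 1 library left out (1 event, of ash2l, without mutant replicate 3; the cause was not tested) and 2, of thop1 and ksr1b, where only events with an SD of exactly 0 counted as constant, since rounding error then lowered the prior variance from 164 to 1.76. Of the values of 79 named genes under these settings, 939 stayed on their side of the threshold, 143 lost the call, 8 gained it and 0 reversed; 44 of the 75 called genes kept the call in every setting. Same-numbered libraries did not deviate together (correlations -0.045, -0.01 and -0.083), so no pairing by number was seen. Deviations from means of 3 libraries cannot exclude a shared batch. With the replicate number as a block 950 genes changed, 620 of them at least 2-fold, and 18 lists moved, with interferon-stimulated genes (adjusted p = 0.0431) and T and NK cell markers (0.0311) added to the 16. The planned count tests were not run, since the deposited values are FPKM. At these depths 1 read of a gene of median length is worth 0.0239 to 0.0277 FPKM, so genes below the 1 FPKM filter are limited by the filter more than by detection.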

Other observations

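Tests chosen only after the result was seen were those of a lower hepatocyte share and of less blood, each as the whole cause, of immediate early genes, and of exon skipping with its alternatives.

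Several groups outside the comparison's main lists held changed genes. In glycolysis and gluconeogenesis 4 genes rose and 7 fell of 32 tested, in the oxidative stress response 6 rose and 2 fell of 29, and neither list passed the camera test. Of 25 tested immediate early genes, a list drawn up after junba, egr1 and atf3 had been seen, 11 rose and 1 fell, with a median log2 fold change of 0.92. The 2 tested genes of the skeletal muscle list both rose, acta1a from 0.0259 to 3.25 FPKM and aldoaa from 10.1 to 32.8.

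A first pattern is genes read in one genotype only: 24 tested genes had at most 3 reads in one genotype and at least 10 in every library of the other, 13 in the wild type and 11 in the mutant. Within 10 Mb of capn3b lay 4 of the 24, cyp2p7, cyp2p9, cyp2p10 and ahsa1a, against 1.59% of the other tested genes (odds ratio 12.4, 95% interval 3.05 to 37.5, Fisher's exact p = 0.000551, two-sided), so a chromosome segment carried along with the mutant allele may account for these 4. Of the 4, 3 are neighbours in a single cluster, which the test counts as independent genes, so the evidence is thin. Of all 181 tested genes within 10 Mb of capn3b 23 changed, against 1268 of 11164 tested genes (11.4%). Neighbouring one-genotype genes also lay elsewhere, such as si:busm1-48c11.3 and zgc:103700 on chromosome 8. The segment around capn3b is not the whole cause: the 95% upper limit of the share near capn3b was 37.4%. For reads moved to a neighbouring copy, 0 of 3 missing genes had a copy moving the opposite way, but all 3 shared the copy cyp2p6, too few to decide; strain differences elsewhere in the genome and an effect of the mutation stay open.

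A second pattern is leukocyte markers higher and erythrocyte markers lower. A lower share of hepatocytes as the whole cause would raise the markers of all other cells alike. It is argued against by the erythrocyte median of -0.682, with mean log2 levels of at most 2.18 in the mutant libraries and at least 2.84 in the wild type libraries. Less blood in the mutant livers as the whole cause is argued against by the neutrophil median of 1.484 and the macrophage median of 0.952, with mean log2 levels of at least 3.08 and 3.18 in the mutant libraries and at most 2.49 and 2.90 in the wild type libraries. These values restate the pattern that prompted the tests: the medians lay beyond all 10000 random lists matched on expression (permutation p = 1e-04, the smallest they can give), but random lists ignore the correlation between members, and the adjusted p = 0.355 for erythrocyte and 0.389 for macrophage and neutrophil markers by camera with an estimated correlation. Less blood for the erythrocyte part alone stays open, since the spread of the erythrocyte log2 fold changes exceeded that of 86.9% of matched lists, short of the 95% set in advance, and more leukocytes or higher expression per leukocyte were not told apart. A lower share of hepatocytes for part of the pattern stays open too. The median was -0.411 for hepatocyte markers and 0.409 for T and NK cell markers. It was 0.311 for stellate cell and fibroblast, 0.183 for cholangiocyte and 0.065 for endothelial cell markers.

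The third pattern concerns genes that react to how and when livers are collected. Among clock genes, the per, cry, nr1d, tef and dbp arm had a median of -0.505 over 11 genes (exact sign-flip p = 0.000977, two-sided), and the bmal, clock and nfil3 arm -0.0545 over 6 genes (exact sign-flip p = 0.625). Opposite movement of the arms had been set in advance as the mark of another time of day. Neither that nor a shared fall was shown. Another time of day need not move the arms in opposite directions, so this result does not argue against it. The sign flips treat genes measured in the same libraries as independent, so these p-values do not measure the spread between libraries. Of the first arm, cry1ab alone passed the threshold singly. Of the immediate early genes, 64% lay higher in every mutant library than in every wild type library, but the list was drawn up after junba, egr1 and atf3 had been seen and holds them, so this share decides nothing. The heat shock list did not pass (camera adjusted p = 0.73). Collection time and handling therefore cannot be told apart from genotype, since no collection times are given in the sources used here, and a response to the mutation stays open as well.

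With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Of the 10 splits 1, the real one, gave as many changed genes (1268, highest other 0) and as many changed at least 2-fold (623, highest other 0). For gene lists the real split gave 16 and the highest other 15, so the list test called many lists under groupings that mix the genotypes, the lowest giving 5. Such groupings widen the spread within groups and keep part of the genotype difference, so their counts of genes and lists are not null counts.

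The splicing event lists gave no exon skipping event past the threshold. Of 1604 events in 1243 genes, 0 differed by limma and 48 had an unadjusted p under 0.05. Among the 906 events that vary, 81 (8.94%) had groups that did not overlap, where chance gives 10% for values without ties. Percent inclusion can be tied between libraries, as at 0%, and ties can lower the chance share. The chance share with ties was not computed, so 8.94% does not tell whether there was an excess. No other tool was run. With the handling of constant events first used, 2 events passed, of thop1 and ksr1b. With a real count of 0, 10 of 10 splits are as large by construction (highest other 0), so the splits say nothing about that count. The 48 events with an unadjusted p under 0.05 were the most of any split, the others giving 24 to 45. With 10 splits, and the others mixing the genotypes, this decides nothing. The smallest p was at an exon of ksr1b (chromosome 15, 31203611 to 31203652), with 53.3% ± 2.1 inclusion in the mutant and 0% in the wild type (SD, n = 3), and an adjusted p of 0.175 by limma; it was singled out after its values were seen, at a lowest summed FPKM of 1.80.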
